A study of Homo sapiens with 6 samples.

How the data were processed

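The deposited files were 6 sparse matrices of raw UMI counts per gene and barcode, 1 for each library, with 33538 genes each. The submitters' processing notes name Cell Ranger 3.1.0 and the human build hg38, while the headers of the deposited matrices give software version 3.0.2; the count values are whole numbers, not normalized by the authors. The libraries were made with a 10x Genomics droplet kit that captures the 3' ends of transcripts and tags each molecule with a UMI, per the labels. Total counts and cells per library are given with the results, and p-values and intervals there cover counting error or the spread between these samples, nothing else. Each tumour, such as OG-03, was taken as 1 donor; cells are not replicates, and the 2 libraries of OG-03 were summed wherever tumours were compared.

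Groups were taken from the library titles, before the data were examined, together with the comparisons, tests, 25 gene lists, markers of 14 cell types and the rule for named genes. The Y-linked genes, XIST and TSIX (130 genes) were dropped at the start. Cells were kept with at least 500 detected genes and under 20% mitochondrial UMIs, where 15813 of 45901 barcodes were under the first limit and 689 at or over the second, some of them both; GBM-07 kept 26.8% of its barcodes. Scrublet scores (scanpy 1.11.5, Python 3.11.15) ranked likely doublets within each library. Its automatic threshold marked 3 of 8621 cells in GBM-06 and 1 of 4971 in GBM-07, so the cells with the highest scores were removed instead, at an expected 0.8% per 1000 barcodes (38, 95, 29, 759, 770 and 643 cells for OG-02, OG-03 LE, OG-03 CO, GBM-05, GBM-06 and GBM-07). That change was made after the automatic calls had been seen; keeping all doublets had been listed as an alternative before.

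Each library was clustered alone: 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9, seed 1). Genes on the GABAergic, interneuron, glutamatergic neuron, channel, receptor and synaptic lists were left out of the variable genes, and none of them is a marker of a class compared here; 5 are markers of mature neurons, a name no cluster took. A cluster's score for a marker list was the mean over markers of log2 CPM (pseudocount of 10 CPM) minus the median over the clusters of all libraries. A cluster took the name of the list with the highest score among lists with at least 3 markers detected in 10% of its cells, if the score reached 1 and its 10 leading genes did not belong to another type; 95 of 98 clusters were named. Classes are therefore rebuilt from markers and are not annotations of the submitters. Arm imbalance was measured as the mean log2 expression of at least 40 genes per autosome arm relative to the immune, vascular and oligodendrocyte clusters of the same library (genes of at least 30 CPM there, ratios limited to 1.5), and a cluster of at least 15 cells counted as imbalanced with at least 2 arms off by 0.43, a value set after the data had been seen. Chromosome positions came from GENCODE 29, in which 32242 gene IDs of the matrices were found on autosomes; that annotation was supplied for this work and is on the same build as the one the notes name, and its release may differ from the one the submitters counted with. How the counting used strand is not given in the sources used here, so overlapping and antisense genes such as DLX6 and DLX6-AS1 are uncertain.

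For tests between classes or tumour codes, counts were summed per tumour and class where at least 20 cells were present, genes were filtered with filterByExpr, libraries were scaled by TMM, and edgeR 4.0.16's quasi-likelihood test (R 4.3.3) was used with Benjamini-Hochberg adjustment at 0.05. OPC-like cells were compared with astrocyte-like and mesenchymal-like cells with the tumour as a block, because both sums come from the same libraries. OG and GBM tumours share no pairing. LE and CO libraries were compared with the code OG or GBM as a term and without a term for the donor. DESeq2 1.42.0 was the second tool. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with the correlation estimated, and with fry, which tests whether a list's genes move one way. No list in any comparison held an adjusted p under 0.05 with an estimated correlation; the lowest was 0.0591, for the mesenchymal list between OPC-like and the other glial cells, whose fry adjusted p was 0.0557. By fry the mesenchymal list passed between the codes in OPC-like cells (0.00407), and in astrocyte-like and mesenchymal-like cells the calcium channel, presynaptic and antigen presentation lists (0.0273 each) and the potassium channel (0.0294) and GABA-A receptor (0.0314) lists. Lists with under 3 tested genes had no list test.

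Named genes were the 10 with the largest fold each way among genes past the threshold with a mean log2 CPM of at least 4, the same sign in every tumour or no overlap between groups, and from each list the 4 members with the smallest p, of which the text gives a part. In the comparison between classes the markers of those classes were not named, and everywhere genes that can show a donor's germline and most clone-like names were not named. Some genes are not reported here, and these were also left out of the search for far values and of the drawings. Where a group had 0 counts, a fold is a lower bound for UMIs pooled over the tumours, against a floor of 3 counts over the group. Deep tumours weigh most in it. With 1 to 3 counts some genes are given the ratio of sums with an exact interval. For the others the UMIs of each group stand unscaled, beside the mean CPM over its tumours. The summed totals differ, as with 24210119 UMIs in OPC-like cells of GBM-05 against 1000260 in OG-02. For OG-03 the rule took 8 genes each way with at least 100 CPM and 30 UMIs in the higher library, and lists of genes of at least 10 CPM were set against 10000 random lists matched on expression. GABAergic shares were counted after thinning each cell to 1000 UMIs. That draw was made anew once, so that the 8 genes and their sum rest on the same molecules, and draws with 200 other seeds are given beside it. Shares have Clopper-Pearson intervals at 95% (scipy 1.17.1), a count of 0 is given the limit of 3 counts over the total, and the share per tumour was compared by exact permutation tests. Other software was numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

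The tests were checked on simulated counts with 200 changed genes drawn from the real means and library sizes. Between OPC-like and the other glial cells 7.4% of genes with a log2 change of 1 were recovered, 83.3% at 2 and 95.5% at 5, and 4.65% of calls were false. Between OG and GBM none, 36.4% and 100% were recovered in OPC-like cells (17.4% of calls false), none, 7.6% and 81.8% in astrocyte-like and mesenchymal-like cells (4.84%), and 1.5%, 27.3% and 98.5% in myeloid-like cells (8.7%). Between LE and CO 5.9%, 53% and 100% were recovered in myeloid-like cells (7.89%) and none, 28.8% and 98.5% in the summed glial cells (10.6%). Alternatives tried were other size factors, no filter on low counts, DESeq2, cells of at least 1000 genes or under 10% mitochondrial UMIs, doublets kept, Leiden resolution 2.0, readout genes kept in the clustering, CO libraries alone, no tumour block and each tumour or library left out in turn. Clusters with arm imbalance alone, and shares without a cluster of mixed markers, were alternatives added after the data had been seen.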

Results

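Single-cell RNA was measured in 6 libraries made from human glioma tissue that had been dissociated into single cells. Each library is named by a tumour code and a region code. There were 2 tumours with the code OG (OG-02 and OG-03) and 3 with the code GBM (GBM-05, GBM-06 and GBM-07), and every library carried the region code CO or LE. OG-03 gave both a CO and an LE library, GBM-05 gave an LE library, and the other tumours gave CO libraries. The codes are used here as names only. The title of the series is about glioma cells that fire action potentials, and the question put to the files was which cell classes carried neuronal, GABAergic and ion channel genes. The matrices held 45901 barcodes and 121728568 unique molecular identifiers (UMIs, each a counted RNA molecule), from 3845928 UMIs in OG-02 to 57717569 in GBM-05. After filtering 27463 cells were kept, between 1817 (OG-03 CO) and 8764 (GBM-05) per library, and the median UMIs per kept cell ran from 1450 in GBM-07 to 4689 in GBM-05.

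Myeloid-like cells, the microglia and macrophages of the tumour, were the most numerous class with 11795 cells. OPC-like cells, which express the genes of oligodendrocyte precursor cells, followed with 4635 and oligodendrocyte-like cells with 4146. There were 2356 astrocyte-like cells, 2026 mesenchymal-like cells, 1448 T or NK cell-like cells, 256 pericyte or fibroblast-like cells, 161 endothelial-like cells, 52 neuronal progenitor-like cells and 30 B or plasma cell-like cells, and 558 cells stayed unnamed. No cluster met the rule for a mature neuron. Gene expression averaged over whole chromosome arms departed from that of the non-glial cells of the same library in 26 of the 30 glial clusters (8932 of 9069 cells) and in 0 of the 63 immune, vascular and oligodendrocyte clusters with at least 15 cells (17819 cells), the classes from which the reference was taken. The 53 OPC-like cells of GBM-06 belonged to the 71 OPC-like cells without such an imbalance. The threshold of this measure was chosen after the data had been seen.

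Oligodendrocyte-like cells, which make myelin, held a larger share of the cells in both OG tumours (33.4% ± 8.06, SD over 2 tumours) than in any of the 3 GBM tumours (10.1% ± 7.51). Pericyte or fibroblast-like cells, the supporting cells of vessel walls, made up 2.16% ± 1.12 in OG and 0.705% ± 0.303 in GBM. The OG value counts a CO cluster of 21 cells in OG-03 whose T or NK cell score (4.61) was close to its own (5.03). Without that cluster, left out after the data had been seen, OG-03 kept 40 of 4456 cells (0.898%), under the 1.02% of GBM-07. Mesenchymal-like cells were found in GBM-05 (3.08%) and GBM-06 (22.4%) and not in the other 3 tumours. Myeloid-like cells ranged from 18.0% in OG-02 to 79.9% in GBM-07, with 34.8% ± 23.8 in OG and 49.9% ± 29.3 in GBM. OPC-like cells ranged from 40.2% in GBM-05 to 0.675% in GBM-06 and 0 of 4328 cells in GBM-07, which allows a share of up to 0.0693%. In GBM-06 a further 204 cells (2.60%) stayed unnamed, with a neuronal progenitor score of 3.08 and an OPC score of 3.07, so its OPC-like share depends on the naming rule. T or NK cell-like cells made up 0.314% ± 0.444 in OG and 5.92% ± 6.55 in GBM.

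An exact two-sided permutation test of the tumour shares gave p = 0.1 for the oligodendrocyte-like and the pericyte or fibroblast-like class, the smallest value that 2 against 3 tumours allow, and 0.6 after adjustment over all classes. In all, 2 of 10 classes had shares that did not overlap between OG and GBM, where chance gives 20% of classes, and this count was defined after the data had been seen. It was 1 without the cluster named above. With a tumour left out chance gives more: the count was 4 without OG-02 and 5 without OG-03 (chance 50% of classes each) and 6 without GBM-07 (33.3%).

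**Figure D1:**
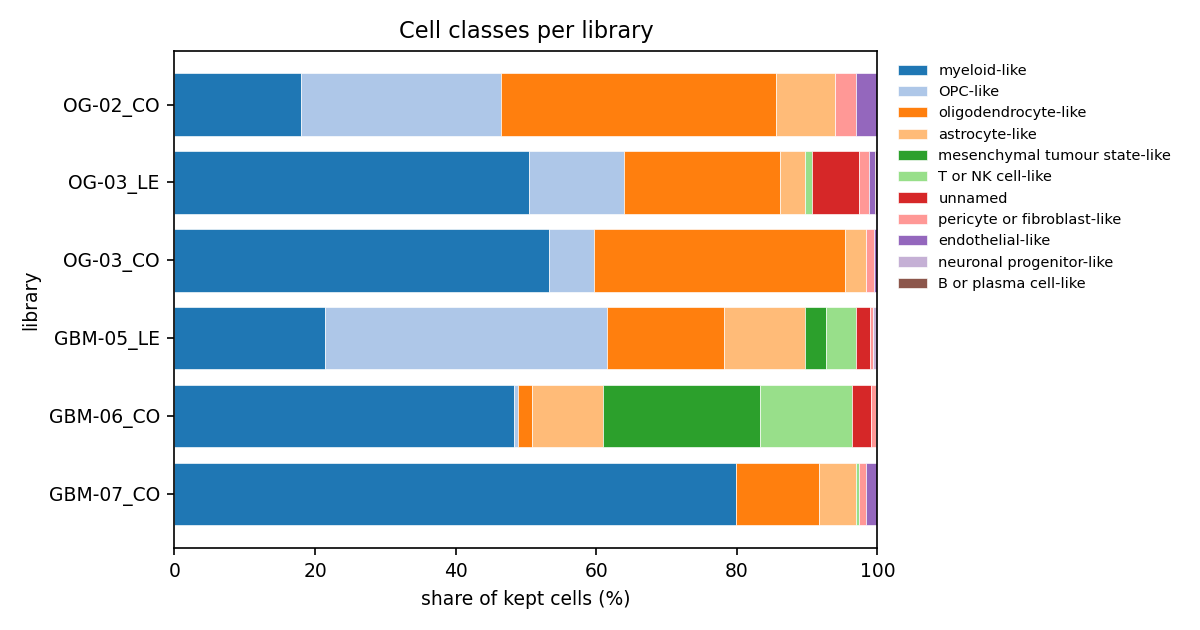
Share of kept cells (percent, horizontal axis) in each named class and in unnamed cells, stacked for each of the 6 libraries on the vertical axis. Myeloid-like cells take up 79.9% of GBM-07, and oligodendrocyte-like cells 39.1% of OG-02 against 1.86% of GBM-06.

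The first tested comparison asked which genes separated OPC-like cells from astrocyte-like and mesenchymal-like cells of the same tumours. It used the 4 tumours with enough cells of both (OG-02, OG-03, GBM-05 and GBM-06). The classes came from clustering these same counts, with only the neuronal, channel, receptor and synaptic lists left out. For all other genes the p-values are therefore not independent of how the classes were made. That holds for the neuronal progenitor, Notch, hypoxia and mesenchymal lists too. OPC-like cells carried far more DLL3 (log2 fold change 6.02 ± 0.76, SE) and DLL1 (3.52 ± 0.36), which encode Notch ligands. Mean DLL3 was 488.5 ± 227.6 CPM (the gene's UMIs scaled to a fixed total of the summed counts; SD, n = 4) in OPC-like cells and 10.5 ± 12.96 in the others. Genes of the oligodendrocyte lineage stood beside them: GPR17 (5.90 ± 0.99), a receptor of committed precursors, and UGT8 (4.71 ± 0.72) and GAL3ST1 (4.39 ± 0.64), enzymes that make the galactolipids of myelin. ZNF488, a zinc finger gene of the same lineage, had 887 UMIs in OPC-like and 1 in the other cells, a CPM ratio of 614.1 (95% counting interval 109.9 to 24280). Lower in OPC-like cells were VIM (−5.41 ± 1.19), an intermediate filament gene, AQP1 (−5.78 ± 0.48), a water channel, IGFBP7 (−5.61 ± 0.65), a secreted protein that binds growth factors, and KCNN3 (−5.81 ± 0.66), a calcium-activated potassium channel. VCAM1, a cell adhesion molecule, had 3 UMIs in OPC-like against 708 in the other cells, a ratio of 0.00293 (0.000604 to 0.00861).

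Other genes at the top of the same ranking were SHD (5.15 ± 0.48), ATCAY (4.98 ± 0.81), SNX22 (4.89 ± 0.67), PLPPR1 (4.87 ± 1.09) and COL20A1 (4.53 ± 0.86) on the OPC-like side. On the other side stood CD38 (−6.003 ± 0.82), which encodes an enzyme that consumes NAD, ADGRV1 (−5.69 ± 1.11), MGST1 (−5.68 ± 0.73), an enzyme of glutathione conjugation, TMEM47 (−5.51 ± 0.78) and LIX1 (−5.46 ± 0.79). Each of the genes named here had an edgeR adjusted p between 0.00412 (SHD) and 0.0478 (PLPPR1) and the same sign in all 4 tumours, which the rule for named genes asked for.

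Of 9 tested genes on the neuronal progenitor list, 4 were higher and none lower: SOX4 (2.56 ± 0.51) and SOX11 (1.34 ± 0.29), transcription factors of young neurons, ELAVL4 (1.97 ± 0.39), a neuronal RNA-binding protein, and MAP2, a microtubule protein of dendrites; 7 were higher when adjusted over the list alone. Most genes of this list also named the neuronal progenitor-like class, which is not compared here. The list's median log2 fold change was 1.97 (camera adjusted p = 7.36e-07; adjusted p = 0.318 with an estimated correlation). Among 8 ionotropic glutamate receptor genes 1 was higher, GRIK2 (2.16 ± 0.26), a kainate receptor subunit, and 2 when adjusted over the list alone, with a median of 1.59. For ionotropic glutamate receptors camera gave an adjusted p of 0.000117, and adjusted p = 0.318 with an estimated correlation. Of 14 postsynaptic and adhesion genes 2 were higher, the scaffold gene DLGAP1 (2.10 ± 0.33) and the synaptic adhesion gene LRRTM2 (2.18 ± 0.46), and 5 when adjusted over the list alone. Postsynaptic and adhesion genes had a camera adjusted p of 0.000108, and adjusted p = 0.318 with an estimated correlation. Of 15 presynaptic genes 1 was higher by either adjustment, over all genes or adjusted over the list alone: RIMS2 (2.35 ± 0.51), an active zone protein. For presynaptic genes camera gave an adjusted p of 0.000151, and adjusted p = 0.318 with an estimated correlation.

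None of the 5 tested voltage-gated sodium channel genes passed over all genes, with SCN3A at 1.85 (edgeR adjusted p = 0.0524) and SCN1A at 1.61 (0.135), and 3 were higher and 1 lower when adjusted over the list alone. Their median was 1.61 (camera adjusted p = 0.0426; adjusted p = 0.433 with an estimated correlation). Of 11 voltage-gated potassium channel genes none passed by either adjustment, over all genes or adjusted over the list alone (median 0.63; camera adjusted p = 0.0191; adjusted p = 0.484 with an estimated correlation). Among 5 voltage-gated calcium channel genes CACNA2D3, an auxiliary subunit, was lower (−2.09 ± 0.45), also when adjusted over the list alone, while the list's median was 0.03 and its mean −0.28 (camera adjusted p = 0.926). Among 4 GABA-A receptor genes GABRB1 was lower (−3.56 ± 0.35), also when adjusted over the list alone, against a list median of 1.59 (camera adjusted p = 0.717). The 3 tested interneuron genes had none past the test over all genes and 1 higher when adjusted over the list alone (median 0.10; camera adjusted p = 0.105). Too few genes for a list test were measured on the GABAergic core (1), glutamatergic neuron (2), inward-rectifier and two-pore potassium channel (2) and erythrocyte (1) lists, and none of their genes passed.

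The mesenchymal list, of which 8 of 16 genes were themselves class markers, was lower in OPC-like cells for 10 of 14 tested genes and higher for none, or 12 when adjusted over the list alone (median −3.56). Mesenchymal genes had a camera adjusted p of 2.96e-16, and adjusted p = 0.0591 with an estimated correlation. Without the class markers 6 of 7 genes were lower, but these genes had also been open to the clustering. Among them were FN1 (−3.70 ± 0.42), an extracellular matrix protein, LGALS3 (−3.87 ± 0.79) and LGALS1 (−3.09 ± 0.61), galectins, and S100A10 (−3.41 ± 0.60). Hypoxia genes, 5 of 16 of which were class markers, had 2 of 14 lower, EGLN3 (−2.86 ± 0.59) and P4HA1 (−1.49 ± 0.26), and 6 when adjusted over the list alone (median −1.35). For hypoxia genes camera gave an adjusted p of 2.35e-05, and adjusted p = 0.344 with an estimated correlation. On the inflammatory cytokine list CXCL2 (−5.999 ± 0.60) and CCL2 (−3.52 ± 0.50), attractants of neutrophils and monocytes, were the 2 of 7 that were lower by either adjustment, over all genes or adjusted over the list alone (median −0.88). Inflammatory cytokines had a camera adjusted p of 0.003, and adjusted p = 0.411 with an estimated correlation.

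Notch pathway genes went both ways: DLL1 and DLL3 were among 4 of 11 that were higher, while HEY1, a target of Notch signalling, was lower (−2.23 ± 0.29), and 4 were higher and 4 lower when adjusted over the list alone. The list's median was −0.75, its mean 0.31, and the camera test leaned up (adjusted p = 0.121). Antigen presentation had 1 of 10 genes lower, TAPBP (−1.18 ± 0.24), and 2 when adjusted over the list alone. For antigen presentation camera gave an adjusted p of 0.00406, and adjusted p = 0.318 with an estimated correlation. Interferon response had none of 11 past the test, and 3 lower when adjusted over the list alone. Interferon response had a camera adjusted p of 0.046, and adjusted p = 0.318 with an estimated correlation. Lipid and phagocytic genes had none of 11, and 4 lower when adjusted over the list alone (camera adjusted p = 0.003; adjusted p = 0.318 with an estimated correlation). Cell cycle genes had none of 9 past either adjustment, over all genes or adjusted over the list alone (median 1.80; camera adjusted p = 0.105). The myelin list had 1 of 5 higher, CNP (1.51 ± 0.32), the microglia list 1 of 4 higher, BIN1 (1.42 ± 0.25), and the macrophage list 1 of 3 lower, TGFBI (−4.70 ± 0.94), with the same counts when adjusted over the list alone. Dissociation stress genes, which are switched on while tissue is taken apart, had 2 of 16 lower by either adjustment, ZFP36 (−3.39 ± 0.46) and ATF3 (−1.91 ± 0.43), with a list median of 0.25 and a mean of −0.21 (camera adjusted p = 0.745).

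Of 10591 tested genes, 495 passed edgeR's quasi-likelihood test with the tumour as a block at an adjusted p of 0.05, 150 higher and 345 lower in OPC-like cells, and DESeq2 passed 1026, which included all 495. The count was 183 without OG-02, 211 without OG-03, 127 without the tumour block, 306 with cells under 10% mitochondrial UMIs and 215 with doublets kept, and 1846 of the unfiltered genes passed.

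**Figure D2:**
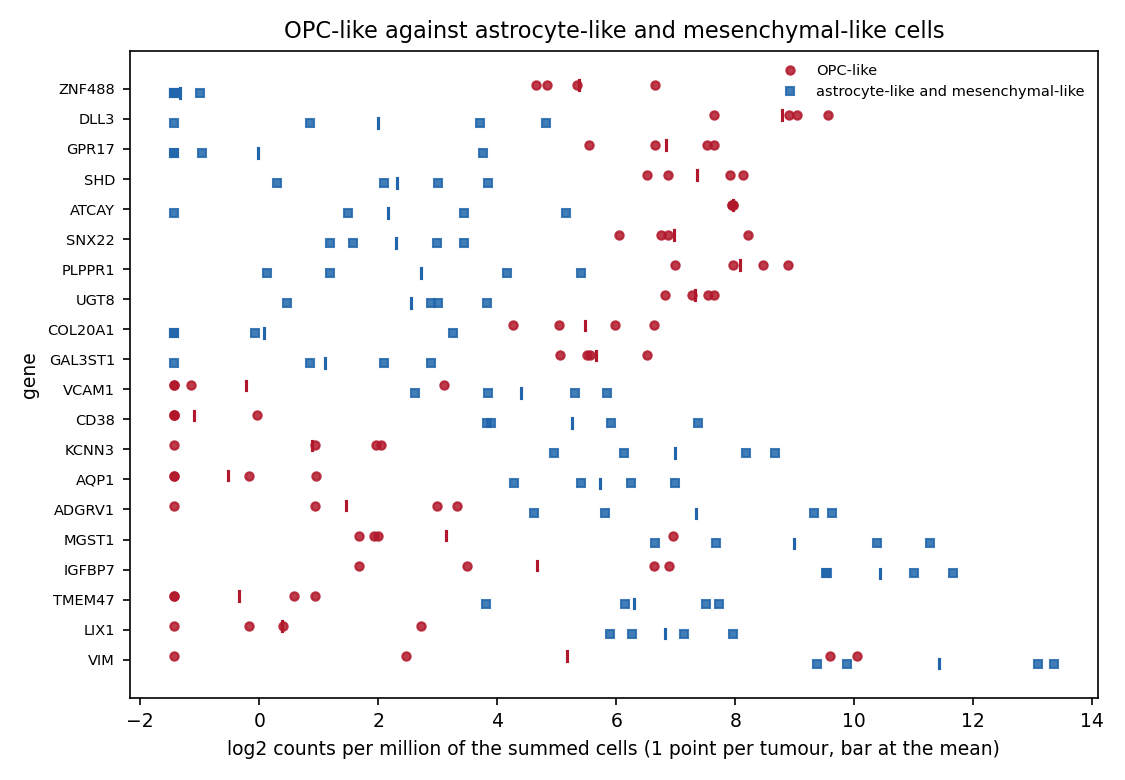
Log2 CPM of summed counts (horizontal axis) of 20 named genes (vertical axis) in OPC-like (circles) and in astrocyte-like and mesenchymal-like cells (squares), with 1 point per tumour and a bar at the mean of the 4 tumours. DLL3 averages 488.5 CPM in OPC-like against 10.5 in the other cells, and genes without a UMI stand at −1.44.

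GAD1, the enzyme that makes GABA from glutamate, was the best covered GABAergic gene. Its level was 22.0 ± 8.30 CPM (SD, n = 4) in OPC-like and 3.24 ± 3.19 in astrocyte-like and mesenchymal-like cells, a log2 fold change of 2.42 ± 0.64 and higher in 4 of 4 tumours, which did not pass over all genes (edgeR adjusted p = 0.0796). The gene (ENSG00000128683) lies on chromosome 2 from 170813213 to 170861151 in GENCODE 29. To compare cells of unequal depth, each cell was thinned to 1000 UMIs and counted as positive with a UMI of any of 8 GABAergic genes, GAD1, GAD2, SLC32A1, DLX1, DLX2, DLX5, DLX6 and DLX6-AS1. Positive OPC-like cells made up 2.89% (95% Clopper-Pearson interval 1.66 to 4.65) of 554 cells in OG-02, 4.31% (2.65 to 6.58) of 464 in OG-03 and 2.03% (1.58 to 2.57) of 3342 in GBM-05. GBM-06 had 2 positive cells of 52, under its floor of 3 cells. In astrocyte-like and mesenchymal-like cells the share was 0.566% (0.228 to 1.16) of 1237 cells in GBM-05 and 0.432% (0.207 to 0.793) of 2314 in GBM-06. OG-02 had 2 positive cells of 161 (0.151 to 4.42%) and GBM-07 1 of 200 (0.0127 to 2.75%), both under the floor of 3 cells, and OG-03 had 0 of 141 (which allows up to 2.13%).

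Myeloid-like cells, which stand for the background of free RNA, had 4 positive cells of 11298 over all tumours (0.0354%, interval 0.00965 to 0.0906), against 106 of 4412 OPC-like cells (2.40%, 1.97 to 2.90). Median UMIs before thinning were 1604, 3394.5, 5859.5 and 1958.5 in the OPC-like cells of OG-02, OG-03, GBM-05 and GBM-06, 1678, 3795, 5902 and 3387.5 in their astrocyte-like and mesenchymal-like cells and 1253, 2592, 5933 and 2079 in their myeloid-like cells. In GBM-07 they were 1756.5 and 1475 in the latter classes. Too shallow to be used were 34, 10, 178 and 1 of the OPC-like cells, 13, 7, 40 and 237 of the astrocyte-like and mesenchymal-like cells and 135, 17, 15 and 239 of the myeloid-like cells, and in GBM-07 32 and 91 of the latter classes. Without thinning the shares were 4.42%, 11.4%, 10.2% and 3.77% in OPC-like cells, 1.15%, 0, 4.70% and 1.02% in astrocyte-like and mesenchymal-like cells and 0, 0.174%, 0.107% and 0.158% in myeloid-like cells, and in GBM-07 2.15% and 0.

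OPC-like cells exceeded the astrocyte-like and mesenchymal-like cells of their own tumour by 2.71 percentage points on average (SD 1.38, 4 of 4 tumours), with p = 0.125 in an exact two-sided sign-flip permutation test, the smallest value 4 tumours allow. Against myeloid-like cells the difference was 3.24 points (SD 1.02, 4 of 4 tumours, exact p = 0.125), and astrocyte-like and mesenchymal-like cells exceeded myeloid-like cells by 0.52 points in 4 of 5 tumours (exact p = 0.125). The draw of thinned UMIs lay high: 12 of 200 other draws reached 2.71 points, and the expected difference over all draws was 2.13. Without thinning the difference was 5.74 points, and with at least 2 UMIs asked of a cell it was 0.015 points. GAD1 supplied most of the signal. Among 4342 OPC-like cells in clusters with arm imbalance, 90 carried a GAD1 UMI after thinning, 10 a DLX2 UMI, 1 a DLX1 UMI and 1 a DLX6-AS1 UMI. After thinning, GAD2, the vesicular transporter gene SLC32A1, DLX5 and DLX6 were found in 0 of those cells. That allows a share of up to 0.0691% each at that depth, and sets no limit on expression. Without thinning, GAD2 was found in 1 of 474 OPC-like cells of OG-03. In the 3520 of GBM-05, DLX5 was found in 2, DLX1 in 11 and DLX2 in 65. In the 1277 astrocyte-like and mesenchymal-like cells of GBM-05, DLX5 was found in 0, DLX1 in 1 and DLX2 in 25. DLX2 stood at 3.38 CPM there against 2.84 in OPC-like cells. DLX1 was also found in 12 of 2551 such cells of GBM-06 and 3 of 232 of GBM-07.

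**Figure D3:**
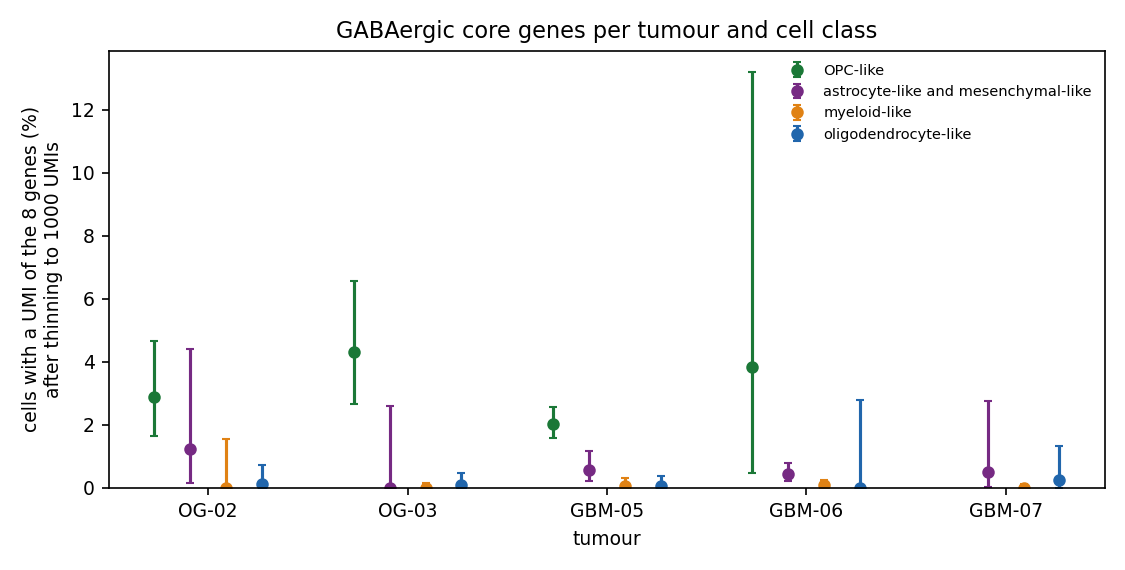
Percent of cells with at least 1 UMI of the 8 GABAergic genes after thinning each cell to 1000 UMIs (vertical axis) in OPC-like, astrocyte-like and mesenchymal-like, myeloid-like and oligodendrocyte-like cells of each tumour (horizontal axis), with 95% Clopper-Pearson intervals as error bars. OPC-like cells lie at 2.89% in OG-02, 4.31% in OG-03 and 2.03% in GBM-05, and myeloid-like cells at 0.0845% or less in every tumour.

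The 2 tumour codes were then compared within OPC-like cells, with OG-02 and OG-03 against GBM-05 and GBM-06. GBM cells carried more VIM (log2 fold change 8.21 ± 0.97; 997 ± 267.7 against 2.88 ± 4.07 CPM, SD, n = 2 each), the fatty acid carrier FABP5 (7.36 ± 0.82) and the growth factor binding protein IGFBP2 (7.09 ± 1.12). EMP1, a membrane protein, was at 62.7 ± 27.3 CPM, GLIS3, a transcription factor, at 41.9 ± 47.0, CDC20, which drives exit from mitosis, at 33.9 ± 35.7 and KIAA0040 at 29.8 ± 17.5, each without a UMI in OG (a floor of 3 counts there is 1.12 CPM). GLIS3 and CDC20 stood at 6.24 and 5.89 log2 CPM in GBM-05. In GBM-06 both stood at 3.17, below the 4.145 that 2 UMIs of GAD1 gave there. OG cells carried more GRIA1 (−7.47 ± 1.55; −1.71 and not past the test without GBM-05), an AMPA receptor subunit, FGF13 (−7.23 ± 0.98), a modulator of sodium channels, and CPLX2, a complexin of vesicle release, with 3 UMIs in GBM against 74 in OG (CPM ratio 0.00456, 0.00092 to 0.0139).

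Also higher in GBM were CDH19, a cadherin, with a CPM ratio of 85.8 (15.3 to 3391) over 1 UMI in OG, and CCDC152 with 1422 against 1 (160, 28.7 to 6325). Also lower was ZNF208 (−7.71 ± 1.17). CACNG2, an auxiliary subunit of AMPA receptors, had 2 UMIs in GBM against 193 in OG (8.69 ± 12.3 against 79.3 ± 38.8 CPM). Its UMIs in GBM all came from GBM-06 (log2 fold change −2.12 and not past the test without GBM-05). RANBP17 had 1 UMI against 203 (0.0227 against 73.9 CPM) and LHX5-AS1 2 against 176 (0.0454 against 81.8). ACTL6B, a chromatin remodelling subunit of neurons, had 1 against 80 (0.0227 against 29.7). SHISAL2B had 3 against 70 (0.0681 against 29.1). Every gene of this ranking had an edgeR adjusted p between 0.00634 (RANBP17) and 0.0497 (CACNG2).

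Presynaptic genes were lower in GBM for 4 of 18 and higher for none: SYT4 (−5.82 ± 0.89), CPLX1 (−6.57 ± 1.04), CPLX2 and SYN1 (−4.43 ± 0.99), all proteins of synaptic vesicles or their release, and 12 were lower when adjusted over the list alone (median −2.06). Without GBM-05, CPLX1 (−2.18) and SYN1 (−1.13) did not pass. Presynaptic genes had a camera adjusted p of 1.95e-10, and adjusted p = 0.359 with an estimated correlation. The neuronal progenitor list had 3 of 11 lower, INA (−5.61 ± 0.68), ELAVL4 (−5.24 ± 0.80) and STMN2 (−4.25 ± 0.80), and 6 when adjusted over the list alone. For neuronal progenitor genes camera gave an adjusted p of 9.19e-08, and adjusted p = 0.230 with an estimated correlation. Of 8 calcium channel genes CACNA2D3 (−5.97 ± 1.14) and CACNA1C (−5.05 ± 1.10) were lower, also when adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.362 with an estimated correlation). Voltage-gated potassium channels had 1 of 15 lower, KCNQ3 (−6.18 ± 1.02), which carries the M current, and 5 when adjusted over the list alone. For potassium channels camera gave an adjusted p of 0.00206, and adjusted p = 0.493 with an estimated correlation. Sodium channels had 1 of 6 lower, SCN3B (−4.13 ± 0.84; −1.86 and not past the test without GBM-05), and 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.137). KCNK3 (−6.27 ± 1.05) was the 1 of 6 inward-rectifier and two-pore channels that was lower, with 2 lower when adjusted over the list alone. GABA-A receptors had 2 of 5 lower, GABRB1 among them, and 3 when adjusted over the list alone. GABA-A receptors had a camera adjusted p of 0.00389, and adjusted p = 0.356 with an estimated correlation. Glutamate receptors had 2 of 10 lower, GRIA1 and GRIN1, and 3 when adjusted over the list alone. For glutamate receptors camera gave an adjusted p of 0.00322, and adjusted p = 0.356 with an estimated correlation. GAD1 averaged 16.2 CPM in GBM and 32.0 in OG and did not pass (edgeR adjusted p = 0.345). GBM-06 had no UMI of KCNQ3, CACNA2D3, CACNA1C, KCNK3, GRIN1 or GABRB1. Their OG means ran from 10.8 CPM (GRIN1) to 18.0 CPM (KCNQ3). At such levels the 108799 UMIs of GBM-06 are too few for that absence to count, so these calls rest on GBM-05.

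The mesenchymal list was higher in GBM for 9 of 12 tested genes, with S100A10 (6.20 ± 0.59), LGALS1 (6.04 ± 0.70) and LGALS3 (6.77 ± 0.80), and for 11 when adjusted over the list alone (median 6.13). Mesenchymal genes had a camera adjusted p of 4.74e-28, and adjusted p = 0.154 with an estimated correlation. Without the class markers 4 of 6 were higher. In the 53 OPC-like cells of GBM-06 these genes stood at a median of 1.16 times their level in the oligodendrocyte-like cells of the same tumour, and in GBM-05 at 5.81 times. Cell cycle genes had 1 of 12 higher, CDC20, and 12 when adjusted over the list alone (median 2.70). The 2 GBM tumours differed: UBE2C and CENPF stood at 7.25 and 9.22 log2 CPM in GBM-05 and had no UMI among the 108799 of GBM-06. CDC20 stood at 5.89 in GBM-05 and at 3.17 in GBM-06. That is below the 4.145 that 2 UMIs of GAD1 gave in the same cells, so the CDC20 call rests on GBM-05. For cell cycle genes camera gave an adjusted p of 1.41e-05, and adjusted p = 0.493 with an estimated correlation. Antigen presentation had 3 of 10 higher, PSMB9 (2.82 ± 0.55), an immunoproteasome subunit, and the class I gene HLA-C (2.30 ± 0.50) among them, and 6 when adjusted over the list alone. Antigen presentation had a camera adjusted p of 1.41e-05, and adjusted p = 0.230 with an estimated correlation. Interferon genes had 2 of 12 higher, IFITM3 (5.93 ± 0.82) and MX1 (4.84 ± 1.04), and 6 when adjusted over the list alone. MX1 stood at 7.58 log2 CPM in GBM-05 and at 3.17 in GBM-06, and IFITM3 at 6.94 and 6.45. For interferon response camera gave an adjusted p of 7.4e-06, and adjusted p = 0.362 with an estimated correlation. The lipid and phagocytic list had 2 of 11 higher, FABP5 and CD9 (3.03 ± 0.49), and 6 when adjusted over the list alone. Lipid and phagocytic genes had a camera adjusted p of 2.2e-06, and adjusted p = 0.230 with an estimated correlation. Of 8 myelin genes 3 were higher, and 4 were higher and 1 lower when adjusted over the list alone. The 3 were CLDN11 (5.61 ± 1.14), MOG (3.46 ± 0.73) and MAG, with 1584 UMIs against 2 (40.3 ± 44.7 against 0.576 ± 0.815 CPM). In GBM-05 CLDN11, MOG and MAG stood at 8.03, 6.09 and 6.17 log2 CPM. In GBM-06 CLDN11 and MAG stood at 3.17 and MOG at 4.145, the level of 2 UMIs, so these calls rest on GBM-05. For myelin genes camera gave an adjusted p of 0.00322, and adjusted p = 0.356 with an estimated correlation. LDHA (4.50 ± 0.68), the lactate dehydrogenase of glycolysis, was the 1 of 14 hypoxia genes that was higher by either adjustment, and no stress gene of 14 passed over all genes. Markers of other cells moved too. Of 3 macrophage genes ITGA4 was higher, with 413 UMIs against 1 (13.7 ± 7.08 against 0.288 ± 0.407 CPM, and 3.17 log2 CPM in GBM-06). All 3 were higher when adjusted over the list alone (camera adjusted p = 8.91e-05, and adjusted p = 0.230 with an estimated correlation). None of 5 microglia genes passed.

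Of 11182 genes 284 passed edgeR at an adjusted p of 0.05, 173 higher and 111 lower in GBM, and 204 of them also passed DESeq2, which called 254. The count was 129 without OG-02, 147 without GBM-05, 2281 without GBM-06 and 2422 in clusters with arm imbalance, which leaves GBM-06 out too; it was 623 with cells of at least 1000 genes, 438 with doublets kept and 1504 without the filter on low counts.

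In astrocyte-like and mesenchymal-like cells, OG-02 and OG-03 were set against GBM-05, GBM-06 and GBM-07. Mesenchymal-like clusters existed in GBM-05 and GBM-06 alone, so the GBM sums mix both classes. Clusters with arm imbalance held 124 of the 174 cells of OG-02 and 132 of the 148 of OG-03, and all cells of the GBM tumours. With those clusters alone 257 genes passed edgeR. GBM cells carried more PLAU, a plasminogen activator, at least 17.3-fold higher, S100A4, a calcium-binding protein of motile cells, at least 20.3-fold, HBEGF, a ligand of the EGF receptor, at least 11.5-fold, and the actin cross-linker FLNC, at least 17.8-fold (UMIs pooled over tumours, floor of 3 counts over the OG group). OG cells carried more ETNPPL (log2 fold change −8.75 ± 0.79; 0.695 CPM in GBM against 439.2 in OG), an enzyme of phospholipid metabolism, GJB6 (−7.73 ± 0.97), a connexin of astrocyte gap junctions, NTSR2 (−7.40 ± 0.90), a neurotensin receptor, and GABRG1 (−8.38 ± 1.21) and GABRB1 (−7.50 ± 0.91), GABA-A receptor subunits.

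The ranking also held DIRAS3 (at least 20.3-fold higher in GBM), ISG20 (at least 15.1-fold), FHL2 (at least 8.89-fold), MREG (at least 8.43-fold) and RRAD (at least 7.6-fold). On the OG side stood SFRP2 (−8.39 ± 1.0), a secreted inhibitor of Wnt signalling, MGAT4C (−7.99 ± 0.81) and RASL10A (−7.34 ± 0.87). TDRD9 had 1 UMI in GBM against 45 in OG (0.0379 against 47.0 CPM), and PRLHR 2 against 42 (0.0790 against 48.9). These genes had edgeR adjusted p values from 0.00514 (ETNPPL, MGAT4C) to 0.0449 (RRAD).

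All 5 tested GABA-A receptor genes were lower in GBM by either adjustment, over all genes or adjusted over the list alone (median −7.50). Among them was GABRD, with 2 UMIs against 30 (0.0790 ± 0.0686 against 33.8 ± 5.43 CPM). GABA-A receptors had a camera adjusted p of 5.97e-13, and adjusted p = 0.175 with an estimated correlation. Interneuron genes had 1 of 3 lower, and 2 when adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.339 with an estimated correlation). Voltage-gated potassium channels had 2 of 5 lower, KCNIP2 (−7.30 ± 0.89) among them, and 3 when adjusted over the list alone. Potassium channels had a camera adjusted p of 4.81e-05, and adjusted p = 0.175 with an estimated correlation. The calcium channel subunits CACNA2D3 (−4.75 ± 0.71) and CACNB2 (−3.99 ± 0.67) were the 2 of 5 that were lower by either adjustment (camera adjusted p = 0.00118; adjusted p = 0.175 with an estimated correlation), and KCNJ16 (−3.68 ± 0.69) was the 1 of 3 inward-rectifier and two-pore channels, with 2 when adjusted over the list alone. Presynaptic genes had 1 of 6 lower, and 3 when adjusted over the list alone. For presynaptic genes camera gave an adjusted p of 0.00659, and adjusted p = 0.175 with an estimated correlation. SHANK2 (−4.87 ± 1.14) was the 1 of 9 postsynaptic genes and HES5 (−4.58 ± 1.001) the 1 of 9 Notch pathway genes that were lower. Each list had 2 when adjusted over the list alone. In clusters with arm imbalance alone none of 9 postsynaptic and none of 3 interneuron genes was lower. Presynaptic genes had 2 of 8 lower there and sodium channels 1 of 4. None of 4 sodium channel genes (median 0.03; camera adjusted p = 0.327), 7 glutamate receptor genes (median −2.52; 0.00107, and adjusted p = 0.339 with an estimated correlation) or 8 neuronal progenitor genes (median −0.08; 0.591) passed over all genes. Over the list alone 1, 2 and none of them were lower.

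Mesenchymal genes were higher for 9 of 14, with ANXA1 (6.12 ± 0.88), TIMP1 (6.47 ± 1.08) and ANXA2 (4.52 ± 0.78), and for 13 when adjusted over the list alone (median 5.15, or 4.89 with genes absent from OG held at their bound). Mesenchymal genes had a camera adjusted p of 7.38e-14, and adjusted p = 0.175 with an estimated correlation. Those 3 genes are class markers of the mesenchymal-like state, and without the markers 3 of 6 genes were higher. Hypoxia genes had 2 of 14 higher, LDHA (4.84 ± 0.71) and ADM, a vessel-dilating peptide, with 2075 UMIs against 3 (CPM ratio 32.3, 11.02 to 156.5), and 7 when adjusted over the list alone. For hypoxia genes camera gave an adjusted p of 0.00228, and adjusted p = 0.471 with an estimated correlation, and without the class markers 1 of 9 was higher (median 1.34). MX1 (4.01 ± 0.88) was the 1 of 12 interferon genes that was higher, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0753). None of the 12 passed in clusters with arm imbalance alone. Antigen presentation had none of 10 past edgeR's test over all genes and 6 higher when adjusted over the list alone. Antigen presentation had a camera adjusted p of 0.004, and adjusted p = 0.175 with an estimated correlation. The lipid and phagocytic list went both ways, with SPP1 (5.89 ± 1.26), osteopontin, higher and LPL (−2.98 ± 0.68), lipoprotein lipase, lower, and 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.279). No gene of 16 on the dissociation stress list passed (median 0.61). The macrophage list had 1 of 3 genes higher, S100A4, and 3 when adjusted over the list alone (camera adjusted p = 0.00107, and adjusted p = 0.175 with an estimated correlation). S100A8 and S100A9 also had no UMI in OG and averaged 58.6 and 153.4 CPM in GBM. Myeloid RNA in these sums was not tested as a source.

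Of 8101 genes 320 passed edgeR at an adjusted p of 0.05, 106 higher and 214 lower in GBM, all of them among the 912 that passed DESeq2. The counts hung on single tumours: 1 gene passed without OG-02 (SSTR2), 3 without OG-03 (NTSR2, ETNPPL and MGAT4C) and 939 without GBM-05. SSTR2, a somatostatin receptor, is named after its values were seen. With CO libraries alone, which also leaves GBM-05 out, 578 passed, against 187 with cells under 10% mitochondrial UMIs, 207 with doublets kept and 1196 without the filter on low counts.

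Myeloid-like cells were compared over the same tumours. Those of GBM carried more genes of macrophages derived from blood monocytes: S100A8 (log2 fold change 7.02 ± 0.81) and S100A9 (6.37 ± 0.77), the subunits of calprotectin, with S100A9 at 1643 ± 889.8 CPM (SD, n = 3) against 20.6 ± 6.12 (n = 2), TGFBI (7.15 ± 0.62), a matrix protein, at 144.6 ± 21.0 against 0.573 ± 0.810, F13A1 (7.23 ± 0.98), a clotting factor made by macrophages, and CD163 (4.78 ± 0.59), a haemoglobin scavenger receptor, at 632 ± 72.2 against 24.7 ± 14.5. CXCL3 and CCL18, chemokines, were at least 69.2-fold and 65.2-fold higher (UMIs pooled over tumours, floor of 3 counts over the OG group). Of the resident microglia list P2RY13 (−1.78 ± 0.37), a nucleotide receptor, and SALL1 (−1.98 ± 0.46), a transcription factor of microglia, were lower in GBM.

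The ranking further held VIM (7.11 ± 0.99), S100A10 (8.83 ± 1.54), NUPR1 (7.18 ± 1.09), a stress-induced regulator, and ATXN8OS (at least 87.8-fold). ADAMDEC1 had 838 UMIs in GBM against 1 in OG (32.3 against 0.0637 CPM), and IGFBP2 723 against 1 (27.5 against 0.832). Lower in GBM were ACY3 (−5.19 ± 0.65), PLAT (−4.99 ± 0.85), the tissue plasminogen activator, EDN1 (−4.96 ± 0.65), endothelin, DHRS9 (−4.60 ± 0.67), CACNA1A (−4.15 ± 0.60), a calcium channel, RTTN (−4.07 ± 0.46), WDR74 (−3.76 ± 0.48) and KBTBD12 (−3.63 ± 0.36). Their edgeR adjusted p values ran from 0.0132 (TGFBI, ADAMDEC1, ACY3) to 0.0459 (CCL18). Of the 839 genes that were higher in GBM, 520 (62.0%, 58.6 to 65.3) also had a higher mean CPM in the astrocyte-like and mesenchymal-like cells of the GBM tumours than in their myeloid-like cells.

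The macrophage list was higher for 11 of 13 and lower for none, and 11 were higher and 1 lower when adjusted over the list alone (median 6.37, or 5.33 with genes absent from OG held at their bound). Macrophage genes had a camera adjusted p of 1.69e-13, and adjusted p = 0.307 with an estimated correlation. S100A8, S100A9, CD163, LYZ and FCN1 of this list, and P2RY12, CX3CR1 and CSF1R of the microglia list, were also among the markers that named the myeloid-like class. The microglia list was lower for 4 of 12, SIGLEC8 (−2.15 ± 0.42) and NAV3 (−1.95 ± 0.50) with the pair above, and 5 when adjusted over the list alone (median −1.24). For microglia genes camera gave an adjusted p of 0.000489, and adjusted p = 0.446 with an estimated correlation. Of 16 cell cycle genes 12 were higher, and 15 when adjusted over the list alone (median 4.79). Among the 12 were TOP2A (5.67 ± 1.06), TYMS (5.25 ± 0.85), CDK1 (587 UMIs against 1, 23.6 against 0.0637 CPM) and RRM2 (438 against 3, 17.1 against 0.191 CPM). Cell cycle genes had a camera adjusted p of 2.62e-10, and adjusted p = 0.404 with an estimated correlation. The mesenchymal list had 10 of 14 higher, TIMP1 (3.61 ± 0.58) among them, and 1 lower, and 12 higher and 1 lower when adjusted over the list alone. For mesenchymal genes camera gave an adjusted p of 8.83e-10, and adjusted p = 0.404 with an estimated correlation. The lipid and phagocytic list had 4 of 12 higher, FABP5 (4.57 ± 0.78), GPNMB (3.42 ± 0.68), a lysosomal glycoprotein, CTSD (2.56 ± 0.48), a lysosomal protease, and APOC1 (2.40 ± 0.57), and 5 when adjusted over the list alone. Lipid and phagocytic genes had a camera adjusted p of 2.28e-05, and adjusted p = 0.307 with an estimated correlation.

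Interferon genes had 4 of 12 higher, ISG15 (4.36 ± 0.96), IFI6 (3.31 ± 0.82), IFITM3 (2.61 ± 0.52) and IFI27 (2.16 ± 0.56), and 7 when adjusted over the list alone. For interferon response camera gave an adjusted p of 0.000982, and adjusted p = 0.518 with an estimated correlation. Antigen presentation had 3 of 12 higher, PSMB8 (2.58 ± 0.43) and PSMB9 (2.38 ± 0.41) among them, and 6 when adjusted over the list alone. Antigen presentation had a camera adjusted p of 0.000489, and adjusted p = 0.446 with an estimated correlation. LDHA (3.27 ± 0.68) and PGK1 (1.85 ± 0.48), enzymes of glycolysis, were the 2 of 15 hypoxia genes that were higher by either adjustment. For hypoxia genes camera gave an adjusted p of 0.0163, and adjusted p = 0.608 with an estimated correlation. Cytokines went both ways: CXCL3 and CXCL2 (642 UMIs against 3, 28.9 against 0.191 CPM) were higher and IL1A (−1.65 ± 0.38) lower. With 2 higher and 3 lower when adjusted over the list alone, the list had a median of −1.02 and a mean of 0.73 (camera adjusted p = 0.347). The stress list was lower as a group (median −1.42; camera adjusted p = 0.00109; adjusted p = 0.466 with an estimated correlation), with EGR1 (−2.21 ± 0.50) the 1 of 16 genes past the test by either adjustment. Calcium channel genes had 1 of 6 higher and 2 lower, CACNA1A and CACNB4 (−2.67 ± 0.44), with 1 higher and 3 lower when adjusted over the list alone. Calcium channels had a camera adjusted p of 0.00754, and adjusted p = 0.404 with an estimated correlation.

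Of 13371 genes 1390 passed edgeR at an adjusted p of 0.05, 839 higher and 551 lower in GBM, and 1366 of them were among the 2480 that passed DESeq2. Without OG-02 no gene passed edgeR (0 genes), and without OG-03 there were 4 (PLAT, AL360012.1 and FP700111.1 among them, the last pair named after their values were seen). It was 280 without GBM-06, 117 with cells of at least 1000 genes, 804 with doublets kept and 2974 without the filter on low counts.

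**Figure D4:**
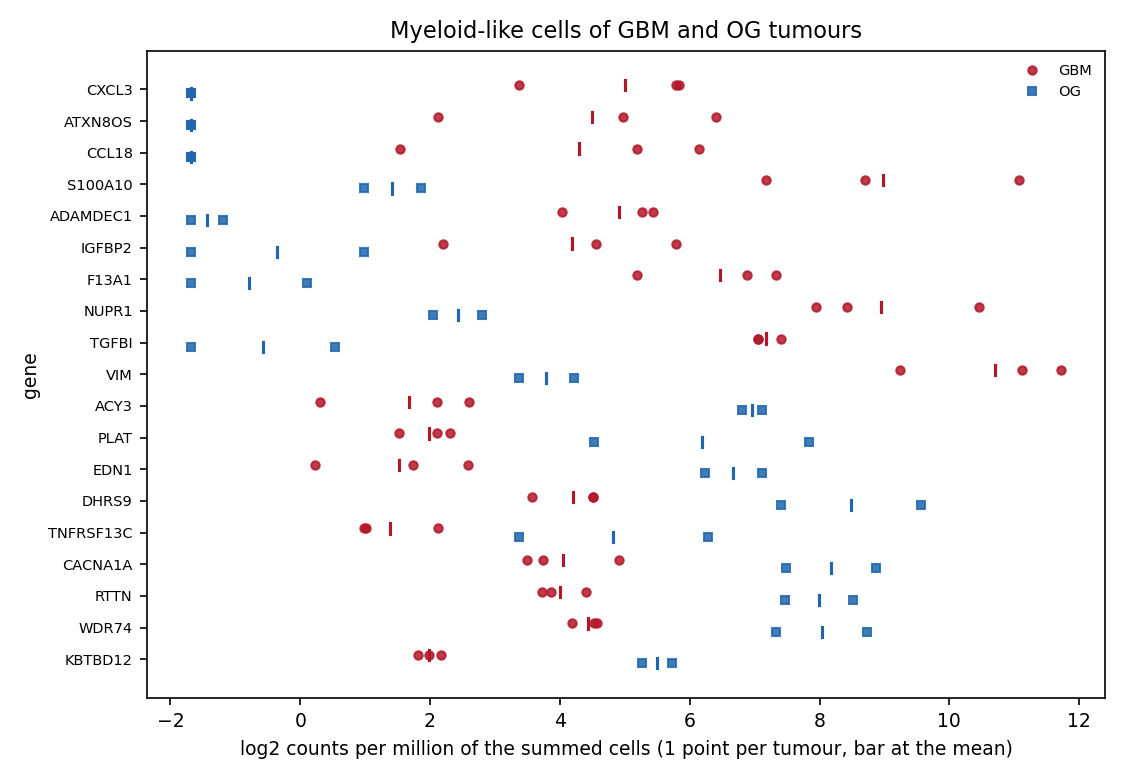
Log2 CPM of summed counts (horizontal axis) of the named genes (vertical axis) in myeloid-like cells of 3 GBM (circles) and 2 OG tumours (squares), with 1 point per tumour and a bar at the mean of the group. TGFBI averages 144.6 CPM in GBM against 0.573 in OG. The groups do not overlap for any gene drawn, because the rule for named genes asked for that.

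The region codes LE and CO could be compared within 1 tumour, OG-03, with 1 library each, so the values below have no replicate check and their intervals cover counting error only. OPC-like cells of the LE library carried more of the myelin protein MBP (CPM ratio 13.1, 6.81 to 28.8), the oligodendrocyte gene BCAS1 (8.92, 3.73 to 27.9), the metallothionein MT3 (4.03, 3.03 to 5.46) and the interferon-induced IFI6 (3.63, 2.58 to 5.27). They carried less of the replication-linked histone HIST1H1B (0.14, 0.0911 to 0.211; with doublets kept it was higher, at a log2 ratio of 2.17), the neuronal gene STMN2 (0.15, 0.0948 to 0.232), the chemokine CCL3 (0.0917, 0.0522 to 0.154) and the immediate early gene IER2 (0.351, 0.315 to 0.393). The median log2 ratio of 11 cell cycle genes was −2.79, below all of 10000 random lists matched on expression, and that of the stress list −1.04, also below all of them, while the myelin list (1.47) and the interferon list (1.07) lay above all. Free RNA from other cells was not tested as a source of these OPC-like values. MBP and MT3 were also higher in myeloid-like cells of the LE library.

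In myeloid-like cells of the LE library the glutamate transporter gene SLC1A2 (35.3, 19.0 to 74.3), MT3 (26.0, 15.5 to 46.9), haemoglobin HBB (12.9, 11.2 to 15.1), the mannose receptor MRC1 (4.57, 4.05 to 5.17) and MBP (3.82, 3.41 to 4.27) were higher. Free RNA from other cells was not tested as a source of these values, and a cluster of 341 myeloid-like cells of that library had an erythrocyte score of 3.095 beside a myeloid score of 1.86. RGCC (0.0591, 0.0471 to 0.0734), CD9 (0.152, 0.114 to 0.199), APOC1 (0.21, 0.195 to 0.225), GPNMB (0.228, 0.177 to 0.29) and LPL (0.262, 0.221 to 0.309) were lower, and all 12 lipid and phagocytic genes were lower (median −1.24, below all random lists). The stress list was higher there (0.62, above all random lists), and lower in oligodendrocyte-like cells (−1.19, 15 of 15 genes, below all), where FOS (0.311, 0.293 to 0.33), EGR1 (0.297, 0.254 to 0.345) and FOSB (0.358, 0.326 to 0.394) were lower and CST3 (14.3, 10.6 to 19.6) and APOE (9.66, 7.77 to 12.1) higher in the LE library. Free RNA was not tested as a source of the oligodendrocyte-like values either. In astrocyte-like cells the cytokine list was lower (median −4.16, 0 of 7 genes higher), with CCL4 at a ratio of 0.0344 (0.011 to 0.0827) and CCL3L1 at least 27.8-fold lower. In cells of at least 1000 genes CCL4 (log2 ratio 1.46), CCL4L2 (1.91) and CCL3 (0.32) were higher in the LE library instead.

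OPC-like cells made up 13.5% (12.2 to 14.9) of the LE and 6.49% (5.41 to 7.73) of the CO library, oligodendrocyte-like cells 22.2% (20.6 to 23.8) and 35.6% (33.4 to 37.9), and myeloid-like cells 50.5% (48.6 to 52.4) and 53.2% (50.9 to 55.5). A further 175 cells of the LE library (6.63%) stayed unnamed, with an astrocyte score of 2.24 and a myeloid score of 2.23, so the direction of the myeloid-like share is open. T or NK cell-like cells made up 1.06% of the LE library, and no CO cluster took that name. The pericyte or fibroblast-like class was not compared, because its CO cluster of 21 cells also held lymphocyte RNA, with 94 UMIs of GNLY and 79 of CCL5. Lymphocytes in the CO library are therefore not excluded.

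Over all 6 libraries, LE (OG-03 and GBM-05) was set against CO (4 libraries) with the code OG or GBM as a term. The donor was not a term, so the 2 libraries of OG-03, 1 on each side, counted as independent. No gene passed edgeR at an adjusted p of 0.05 in myeloid-like cells (0 of 13225, 540 at an unadjusted p under 0.05, 1 by DESeq2, the chemokine CCL18, named after its value was seen) or in OPC-like, astrocyte-like and mesenchymal-like cells summed (0 of 12059, 630 unadjusted, 73 by DESeq2). In myeloid-like cells the interferon list (median log2 fold change 0.88, camera adjusted p = 0.000302) and the stress list (0.74, 2.2e-05) leaned to LE. The myelin list leaned to CO (−1.02, 0.0138). Each had adjusted p = 0.911 with an estimated correlation. Within OG-03, IFIT3 (log2 CPM 3.70 in LE, 4.08 in CO), IFIT2 (5.30, 5.41) and IFI44L (5.82, 5.97) were lower in LE and IRF7 (5.07, 4.78) higher. Each of these was highest in GBM-05. MOG (3.58) and KLK6 (3.55) of the myelin list were highest in GBM-07. The summed glial cells differed in class: OPC-like cells were 356 of 448 and 3520 of 4797 cells in the LE libraries of OG-03 and GBM-05. In the CO libraries of OG-03 and GBM-06 they were 118 of 174 and 53 of 2604, OG-02 had 588 beside 174 astrocyte-like cells, and GBM-07 had none. In these sums the cytokine list (−2.93; 8.43e-07), the macrophage list (−3.43; 2.9e-06) and the mesenchymal list (−1.45; 3.72e-05) leaned to CO, each with adjusted p = 0.559 with an estimated correlation, and 6 cytokine genes and 4 macrophage genes were lower in LE when adjusted over the list alone. The lipid and phagocytic list (−0.72, camera adjusted p = 0.0117) also leaned to CO. To LE leaned the Notch (1.11, 0.003), postsynaptic and adhesion (0.80, 0.00636), interferon (0.75, 0.00868) and ionotropic glutamate receptor (1.03, 0.0117) lists. With an estimated correlation camera gave these lists an adjusted p of 0.559, or 0.640 for glutamate receptors. CCL2 (−4.89 ± 0.88), S100A9 (−4.71 ± 0.76) and DLL3 (4.25 ± 1.28) had edgeR adjusted p values of 0.565, 0.594 and 0.884. Without the LE library of OG-03, 39 genes passed in the summed glial cells, and without the filter on low counts 312 there and 88 in myeloid-like cells.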

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

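No test in this part was chosen after its result had been seen, and no explanation was tested. Of 210 groups of samples checked for a value far from the rest, 13 had one, and chance alone gives about 1 in 20. Values are log2 CPM of summed counts, in which a gene with no UMI stands at −1.44.

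GBM-06, with 53 OPC-like cells, stood apart from the other 3 tumours in that class for VCAM1 (3.11, others −1.44 to −1.16), MGST1 (6.96, others 1.68 to 2.0) and TGFBI (4.08, others −1.44 to −0.53). With 108799 UMIs in that sum, these values rest on 1, 15 and 2 UMIs. It was the 1 tumour without a UMI of NEUROD1 (−1.44, others 3.29 to 4.196) and KCND2 (−1.44, others 5.74 to 6.11). OPC-like cells of GBM-05 were high in MBP (9.40, others 7.54 to 7.70), and held CD38 at −0.04 and CXCL2 at −0.53 (15 and 8 of 24210119 UMIs). The others, with at most 1730227 UMIs, had none of either gene, and at that depth such low levels may give no UMI.

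In astrocyte-like and mesenchymal-like cells GBM-05 was high in GPR17 (3.76, others −1.44 to −0.96) and GABRB2 (3.03, others −1.44), and its ZNF488 value of −1.005 came from the only UMI of the gene in that class. GBM-06 was low in RIMS1 (−0.32, others 2.61 to 2.96) and high in SLC2A1 (6.53, others 4.42 to 4.64), a glucose transporter on the hypoxia list.

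The difference between OPC-like and the other glial cells went opposite ways in the 2 codes for 2 of 103 genes, and the difference between the codes was not tested. ERBB4, a neuregulin receptor, was lower in OPC-like cells of both OG tumours (−1.95) and higher in those of both GBM tumours (1.94), a gap of −3.89. KCNJ10, a potassium channel of astrocytes, had −0.52 and 1.76, a gap of −2.29.

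The unnamed cells, which enter no comparison, had GABAergic UMIs in 6 of 446 thinned cells, all of GAD1 (1.34%, 95% interval 0.495 to 2.90).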

How the results depend on the processing

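Clusters with arm imbalance alone, shares without a CO cluster of OG-03, the expected share over all draws and readout genes kept for the GABAergic share were tests chosen after the data had been seen; all other alternatives were planned. OG and GBM tumours share no donor and LE and CO share 1, so neither comparison was paired; OPC-like and the other glial cells were paired by tumour. Without the tumour block the count between OPC-like and the other glial cells was 127 instead of 495. Other size factors and Leiden resolution 2.0 kept every count of genes within 1.5 times its value. Where a left-out tumour leaves 1 in a group, that tumour is assumed to vary like the others. The cause was not tested for any change named here.

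Without the filter on low counts the counts were 1846 (OPC-like against other glial), 1504 (OG against GBM, OPC-like), 1196 (astrocyte-like and mesenchymal-like), 2974 (myeloid-like), 88 (LE against CO, myeloid-like) and 312 (LE against CO, glial), more genes being tested. DESeq2 gave 1026 in the first, 912 between the codes in astrocyte-like and mesenchymal-like and 2480 in myeloid-like cells, and 1 and 73 for LE against CO. Under 10% mitochondrial UMIs gave 306 in the first and 187 in astrocyte-like and mesenchymal-like cells. Doublets kept gave 215, 438, 207 and 804 in the first 4. Cells of at least 1000 genes gave 623 in OPC-like and 117 in myeloid-like cells between the codes, CO libraries alone 578 in astrocyte-like and mesenchymal-like cells, and clusters with arm imbalance 2422 in OPC-like cells.

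With each tumour or library left out the counts ran from 183 to 726 in the first comparison, 129 to 2281, 1 to 939 and 0 to 1549 between the codes in OPC-like, astrocyte-like and mesenchymal-like, and myeloid-like cells, 0 to 0 for LE against CO in myeloid-like and 0 to 39 in glial cells, 2 to 6 for classes without overlap (1 without the pericyte or fibroblast-like CO cluster of OG-03), and 2.18 to 3.12 points for the GABAergic share. That share's difference was 5.74 points without thinning, 0.015 with at least 2 UMIs, 3.46 with 2000 UMIs, 2.33 with doublets kept, 2.72 with GAD1 and GAD2 alone, 2.21 in clusters with arm imbalance and 2.69 with readout genes kept.

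Of 2740 values of named genes with a tumour left out, 2165 kept sign and side of the threshold, 343 no longer passed, 110 newly passed and 122 moved otherwise; of 4860 under other settings 4225, 249, 322 and 64 did, and none turned sign past the threshold. Within OG-03, 211 of 244 values held, 28 moved and 5 turned sign: on the log2 scale of LE over CO, HIST1H1B in OPC-like cells was 2.17 with doublets kept, and in astrocyte-like cells of at least 1000 genes CCL4 was 1.46, CCL4L2 1.91, CCL3 0.32 and RGS1 2.40. The pericyte or fibroblast-like class gave no value for OG-03 at 1000 genes. Depth was low in the 53 OPC-like cells of GBM-06 (108799 UMIs) and in GBM-07 and OG-02 (medians of 1450 and 1590 UMIs per kept cell).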

Other observations

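In this part, tests chosen after the results were seen were the free RNA test of the GABAergic share, the test of shallow cells and the other splits of the samples. So was every value from clusters with arm imbalance alone. The other tests of this part were written before. The count of classes without overlap, given above, was also defined after the data had been seen.

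Restricted to clusters with arm imbalance, OPC-like cells carried more cell cycle RNA than astrocyte-like and mesenchymal-like cells: 7 of 9 genes were higher (median log2 fold change 3.93; camera adjusted p = 1.94e-11), where none of 9 passed with all clusters. That restriction also left GBM-06 out, so 3 tumours were compared instead of 4. Leaving out GBM-06 alone, with all clusters, passed 726 genes, against 692 with the restriction. For the cell cycle list no count of that run is given here, so for it the 2 changes are not told apart. The neuronal progenitor list had 5 of 10 higher there (camera adjusted p = 1.62e-07) and ionotropic glutamate receptors 3 of 8 (camera adjusted p = 0.00167), and 7 of 9 mesenchymal genes were lower. An estimated correlation was not run for these lists within the restriction. With all clusters the cell cycle list had an estimated correlation of 0.846, and a camera adjusted p of 0.647 with it. The value of 1.94e-11 came from the preset correlation, so no conclusion is drawn from it. Cell cycle, neuronal progenitor and mesenchymal genes had also been open to the clustering. Their differences are therefore not independent of how the classes were made. Of 102 positive OPC-like cells with arm imbalance 90 had GAD1, and among 20 positive astrocyte-like and mesenchymal-like cells 7 had GAD1, 6 DLX1, 5 DLX2 and 2 GAD2. In 70 OPC-like cells without arm imbalance 4 were positive (5.71%, 1.58 to 14.0), all with GAD1, and 1 of 50 neuronal progenitor-like cells was.

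GABAergic UMIs in OPC-like cells may come from free RNA or from doublets with neurons, or may reflect transcription in the cells. Free RNA would give the classes similar shares. With cells pooled over tumours, the lower bound in OPC-like cells was 21.8 times the upper bound in myeloid-like cells. Within OG-03 the intervals were 2.65 to 6.58% against 0 to 0.161%, and within GBM-05 1.58 to 2.57% against 0.00136 to 0.299%. They lay closer in OG-02 (1.66 to 4.65% against 0 to 1.54%). In GBM-06 they were 0.469 to 13.2% (2 positive cells) against 0.0174 to 0.247%. Doublets with neurons would bring mature neuron genes, but OPC-like cells with a GABAergic UMI had 1.013 times (0.875 to 1.16) the neuron marker UMIs expected from the others, and 1 of 442 had a GAD2 or SLC32A1 UMI. These values argue against free RNA as the whole cause in OG-03 and GBM-05, and are less clear in OG-02 and GBM-06. Of the 442 positive cells 360 came from GBM-05, 54 from OG-03, 26 from OG-02 and 2 from GBM-06. The interval of the neuron marker ratio came from resampled cells and does not cover the spread between tumours. For the pooled cells, mostly of GBM-05, that ratio argues against doublets with neurons as the whole cause. It was not taken for single tumours. Transcription in the cells themselves stays open: the design holds no group that tests it, so no biological explanation was tested.

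Genes higher in GBM than in OG in myeloid-like cells could come from RNA of neighbouring tumour cells, from shallow cells or from other myeloid states. Of the called genes 62.0% (58.6 to 65.3) had a higher mean CPM in astrocyte-like and mesenchymal-like than in myeloid-like cells of GBM, between the bounds set for and against such RNA, so it cannot be told apart from expression for this set. With cells of at least 1000 genes the median log2 fold was 1.37 instead of 1.495, a ratio of 0.919, with 100% of genes of the same sign. The genes were chosen as higher with all cells, and the deeper cells are part of those sums, so a shared sign was largely given. The values show that the median fold was nearly kept without the shallower cells. They do not exclude shallow cells as a source. The count of calls was 117 in the deeper cells instead of 1390, so the calls themselves were not kept. The difference between the codes named in the design stays open, as untested.

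Mesenchymal genes of OPC-like cells in GBM may likewise come from free RNA. In GBM-05 the 9 called genes had a median of 5.81 times (quartiles 3.70 to 12.04) their level in oligodendrocyte-like cells of the same tumour, which argues against free RNA as the whole cause there. In GBM-06 the median was 1.16 times (0.939 to 1.496), which is consistent with free RNA in its 53 OPC-like cells. Without GBM-06 the comparison of the codes in OPC-like cells passed 2281 genes.

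The real split between OPC-like and the other glial sums passed 495 genes, and the highest of the other splits 0. So 1 of 32 estimable splits (of 35) gave as many. Only 8 splits part the classes within every tumour as the real one does, too few for a share under 0.05. The classes came from clustering the same counts, so a high count for the real split was largely fixed in advance.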
